A study of Salmonella enterica subsp. enterica serovar Typhimurium str. SL1344 and Bacteroides thetaiotaomicron VPI-5482 with 40 samples.

How the data were processed

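The libraries were made from total RNA of 2 gut bacteria. Salmonella enterica serovar Typhimurium SL1344 was grown to an OD of 2.0 and Bacteroides thetaiotaomicron to an OD of 0.5. Per the labels, cDNA was made with an NEB small RNA kit after fragmentation of the RNA, or with a Takara SMARTer Pico kit, and ribosomal cDNA was cleaved in some libraries with Cas9 and a pool of single guide RNAs (sgRNAs) against rRNA, a procedure called DASH. The labels give for each library the RNA input, the clean-up after cleavage (column or proteinase K) and the excess of Cas9 and sgRNA over cDNA, written here as cDNA:Cas9:sgRNA. The deposited tables hold expected counts per annotated feature, which are partly fractional and not scaled for depth. The fractions were read here as reads shared between positions or features, which the sources do not state, nor do they state whether the reads of both kits were counted in the same way. Adapters were trimmed with cutadapt 2.5 according to the submitters' processing notes. The aligner and the read counter are not given in the sources used here.

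The Salmonella table held 5002 features, of which 22 were rRNA genes (7 of 16S, 7 of 23S and 8 of 5S), 86 were tRNA genes, 171 were small RNAs (sRNAs) and 4723 were coding sequences. The Bacteroides table held 5147 features with 15 rRNA genes, 71 tRNA genes, 245 sRNAs and other noncoding RNAs and 4816 coding sequences. A repeated header line in the Bacteroides table was left out. Identical gene copies have near-equal values in the deposited counts and are taken to share reads, so values of tRNA copies and of rRNA operon spacer RNAs are not independent of each other. Depth lay after rounding to whole numbers between 4281313 and 13295575 counts per Salmonella library, with 225024 to 4067815 outside rRNA, and between 7926857 and 14641136 per Bacteroides library, with 2708775 to 7727589 outside rRNA. The widest 95% exact Clopper-Pearson interval of a single library's rRNA share was 0.092 percentage points in Salmonella and 0.055 in Bacteroides. Such intervals, and the floor of 3 counts used where a group was at 0, cover counting error only.

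Libraries of the input, ratio and preincubation series were analysed within their own series. In the excess series the NEB and Takara libraries of a species were fitted together with kit as a term, and the slope with Cas9 excess was taken within 3 series, which differ in species, kit and guide pool (797 sgRNAs for Salmonella and 651 for Bacteroides), and averaged. In the input series each DASH library was paired with the undepleted library that, by the labels, had the same RNA input and clean-up. The rRNA measure was the log2 ratio of rRNA counts to all other counts, and the difference within 8 pairs was tested with an exact two-sided sign-flip permutation test. The same test within RNA input compared the clean-ups. Relations with RNA input, Cas9 and sgRNA were given as Pearson's r and Spearman's rho with exact two-sided permutation p, and Benjamini-Hochberg adjustment over the 3 relations of the ratio series. The slope of the rRNA ratio with Cas9 excess was tested by exact permutation of 9 DASH libraries within 3 series. For gene detection every library of the input series was thinned at random to 7228577 counts, the smallest total, and non-rRNA genes with at least 10 counts were counted out of 4980.

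Gene tests used edgeR 4.0.16 in R 4.3.3. Counts were rounded to whole numbers, rRNA genes were left out before library sizes were taken, low counts were removed with filterByExpr at its defaults, and TMM factors and the quasi-likelihood F test were applied with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Pairs were a block for DASH against no DASH in the input series. Blocks of the same RNA input and treatment were used for proteinase K against column, and blocks of the same excess for Takara against NEB in Bacteroides. DASH and clean-up were covariates of the trend with log10 RNA input, kit was one for DASH in the 2 excess series, and DASH was one for kit in the Salmonella excess series. Interactions tested whether the DASH effect differed with clean-up, RNA input or kit. The lone undepleted library of the ratio series was assumed to vary like its 7 DASH libraries. The p-values of the gene tests and of the exact tests measure spread between libraries only. No p-value covers spread between cultures, since the labels name no separate cultures.

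Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. Camera compares a list with all other genes. Its p at the preset correlation thus measures spread between genes, and genes that share reads or move together can make it too small. Fry tests whether a list moves one way and does not compare it with other genes. The Salmonella lists were tRNAs (86 matched), rRNA operon tRNAs (14, which are also among the tRNAs), housekeeping noncoding RNAs (6), sRNAs associated with the RNA chaperones Hfq and ProQ (31), ribosomal proteins (51), the invasion island SPI-1 (33), the intracellular island SPI-2 (30), flagella and chemotaxis (52), heat shock and chaperones (14), outer membrane proteins (14) and ATP synthase (9). The Bacteroides lists were tRNAs (71), ribosomal proteins (53) and noncoding RNAs (245). The lists for the starch utilisation (sus) operon and the capsule loci CPS1 to CPS8 are not analysed here, since no file paired their locus tags with the table's identifiers (0 matched).

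Genes named in the text were taken by a fixed rule for the comparisons of the input series and of Bacteroides. Those with adjusted p under 0.05, a mean of at least 10 CPM (of non-rRNA counts) and the same direction in every pair (input series), or in both kits or all excesses (Bacteroides), gave the 10 largest rises and the 10 largest falls. With fewer than 5 such genes, all pairs but 1 sufficed. The 4 members of each list with the smallest p, the rRNA classes and the housekeeping noncoding RNAs were added. Genes named for the ratio and excess series of Salmonella lie outside this rule and were chosen after their values were seen. Where tRNA or protein copies share a symbol, the start position on the chromosome is given.

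The comparisons, tests, lists and naming rule, and most alternatives, were fixed before the data were examined. The alternatives were DESeq2 1.42.0 with its size factors, edgeR with relative log expression factors or library sizes alone, no filter on low counts, rRNA genes kept, tRNA genes left out, libraries thinned to the smallest non-rRNA total, no block, leaving out each library or pair in turn, and other definitions of the rRNA ratio. Alternatives without the 0.4 ng libraries, or with the 800.3 and 59.3 ng libraries alone, were added after the data had been seen, because the 0.4 ng libraries listed counts for far fewer genes. The gene tests at their fixed settings, and those of DASH and of the trend without the 0.4 ng libraries, were run on simulated data, in which 100 genes changed by a log2 of 1 and 100 by a log2 of 2 in counts drawn with the fitted means and dispersions (seed 7). For the trend and the DASH effect by RNA input these changes were per 10-fold input. Splits of the libraries into other groups of the same sizes, at most 100, were run for comparisons with at least 3 libraries per group. Tables and exact tests were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.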

Results

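The data were read counts per gene in 40 RNA-seq libraries of total RNA, 32 from Salmonella and 8 from Bacteroides. The experiments asked how far Cas9 cleavage of ribosomal cDNA (DASH) lowered rRNA reads under different reaction conditions, and whether other transcripts kept their relative abundance. The Salmonella input series held 16 NEB libraries, with and without DASH at 1:100:1000, at 4 RNA inputs (0.4, 5.3, 59.3 and 800.3 ng) and with 2 clean-ups. The ratio series held 8 NEB libraries from 180 ng RNA, 1 without DASH and 7 with different Cas9 and sgRNA excesses. A pair from 400 ng held 1 DASH library with preincubation of the reaction and 1 undepleted library. By the labels the DASH libraries of the input and excess series were preincubated too, and those of the ratio series were not. The guide pool held 113 sgRNAs in the ratio series and the preincubation pair, 797 in the input series and the Salmonella excess series, and 651 in Bacteroides, so that series differ in more than preincubation. The excess series held 4 NEB libraries (6.5 to 8.2 ng) and 2 Takara libraries (1 ng) of Salmonella, and 4 NEB libraries (4.5 to 6.7 ng) and 4 Takara libraries (1 ng) of Bacteroides. Total counts of the input series were 10916390 to 13295575 without DASH and 7228577 to 9098148 with it, and the other Salmonella libraries held 4281313 to 12261551 counts. The Bacteroides libraries held 7926857 to 14641136 counts.

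In the Salmonella input series, rRNA took 94.96% ± 1.04 (SD, n = 8) of counts without DASH and 56.5% ± 4.96 (SD, n = 8) with it. The ratio of rRNA to other counts fell in all 8 pairs by a mean log2 of 3.88 ± 0.53 (SD), which is 14.7-fold, with single pairs between 8.19-fold and 20.4-fold (exact sign-flip permutation test, n = 8 pairs, p = 0.0078125, the smallest this design allows). The share left for all other RNAs was 8.99-fold larger (SD 2.17, n = 8, range 5.55 to 11.01). 16S rRNA, the RNA of the small ribosomal subunit, changed from 35.3% to 20.2% of counts (log2 ratio to other counts -3.93 ± 0.54 SD). 23S rRNA of the large subunit changed from 58.7% to 35.6% (-3.85 ± 0.52 SD), and 5S rRNA, the short RNA of the large subunit, from 0.933% to 0.69998% (-3.58 ± 0.63 SD). 5S rRNA was depleted less than 23S rRNA by a log2 of 0.27 (SD 0.17) and 16S more by a log2 of -0.08 (SD 0.044), each in the same direction in 8 of 8 pairs (exact permutation p = 0.0078 for each, n = 8). These tests take the 8 pairs as independent. The pairs come from 4 RNA inputs with 2 clean-ups each, and with the 4 inputs as units such a test cannot come under 0.05.

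**Figure D1:**
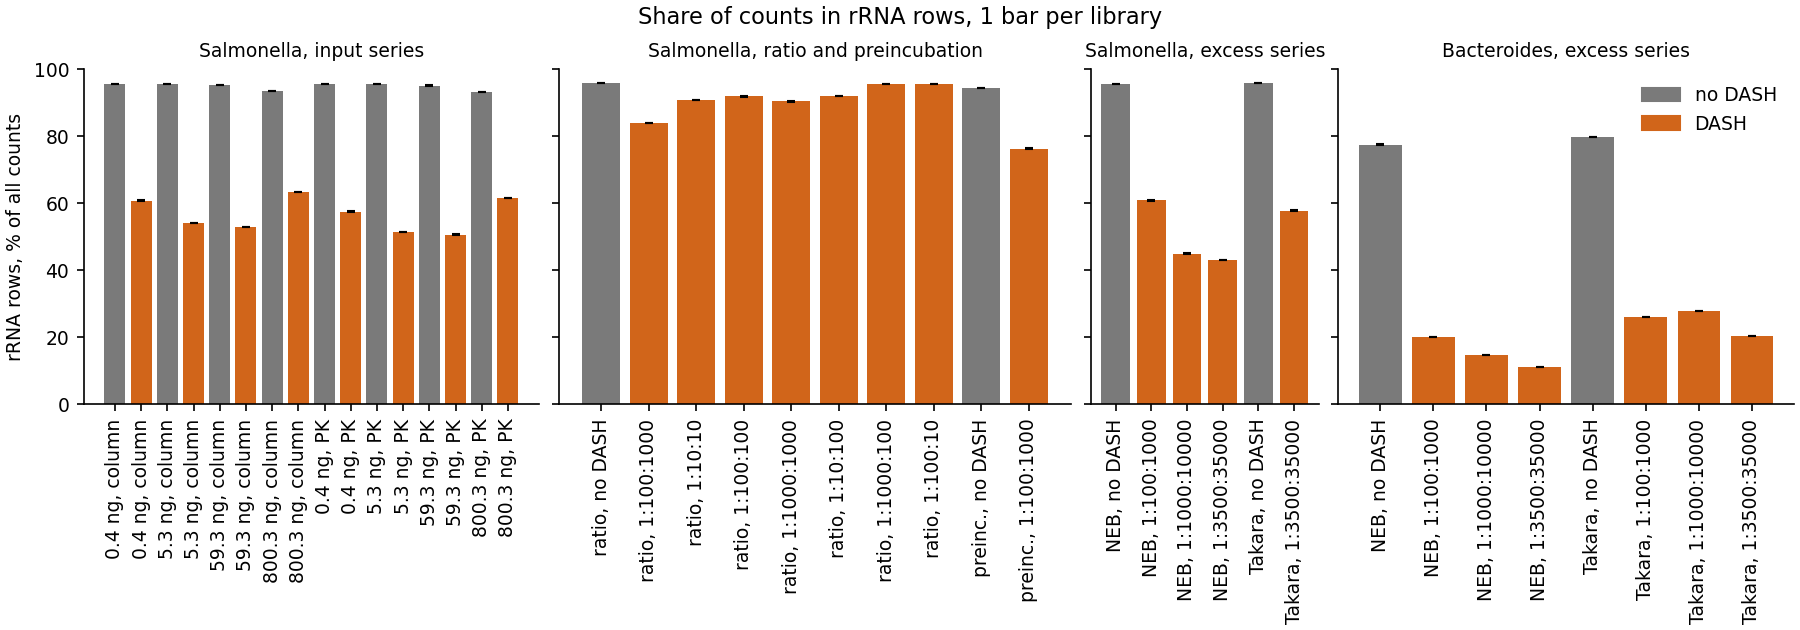
Share of counts in rRNA genes (y axis, percent of all counts) in each of the 40 libraries, 1 bar per library, grey without and orange with DASH, with black 95% Clopper-Pearson intervals; PK is proteinase K, preinc. the preincubation pair and 1:x:y the ratio of cDNA to Cas9 to sgRNA. Bars of the input series lie between 93.2 and 95.7% without DASH and between 50.6 and 63.4% with it, and the lowest bar is Bacteroides NEB at 1:3500:35000 with 11.03%.

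The clean-up after cleavage was compared at each RNA input. After the column the mean log2 change was -3.82 (SD 0.55, n = 4) and after proteinase K digestion it was -3.93 (SD 0.57, n = 4). Proteinase K gave the larger depletion at 4 of 4 inputs, by a mean log2 of -0.11 (SD 0.050, exact permutation test, which 4 inputs cannot bring under 0.05). By RNA input the mean rRNA change was -3.93 at 0.4 ng, -4.30 at 5.3 ng, -4.21 at 59.3 ng and -3.07 (8.37-fold) at 800.3 ng. Across the 8 pairs the change showed no relation with log10 RNA input that passed the threshold (r = 0.61, exact permutation p = 0.112, rho = 0.34, p = 0.422). Without the pairs farthest from the median input, both at 800.3 ng, r was -0.68 (exact permutation p = 0.144), so that the positive r rested on those pairs. Without the 0.4 ng pairs, a choice made after the data were seen, r was 0.90 (exact permutation p = 0.0222, n = 6). These 6 pairs come from 5.3, 59.3 and 800.3 ng with 2 clean-ups each, and pairs of the same input lay close together. They are not 6 independent units, so this p is not read as a relation with input.

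More genes were seen after DASH at equal depth. With every library thinned to 7228577 counts, non-rRNA genes with at least 10 counts were 1.59-fold more numerous in DASH libraries (mean log2 0.67, SD 0.38, 7 of 8 pairs higher, exact permutation p = 0.0156, n = 8). This test, too, takes pairs of the same RNA input as independent. At 5.3 to 800.3 ng, 2130 to 2264 genes were seen without DASH and 3865 to 4188 with it. At 0.4 ng the numbers were 1484 and 1457 after the column and 1970 and 2165 after proteinase K, and without these pairs the mean log2 was 0.87. Within the non-rRNA counts, the shares of tRNAs, sRNAs and coding genes with and without DASH differed by less than the spread between pairs. The mean log2 difference was -0.03 for tRNAs (SD 0.065, exact permutation p = 0.211, n = 8), 0.0022 for sRNAs (p = 0.922) and 6.1e-05 for coding genes (p = 0.992).

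**Figure D2:**
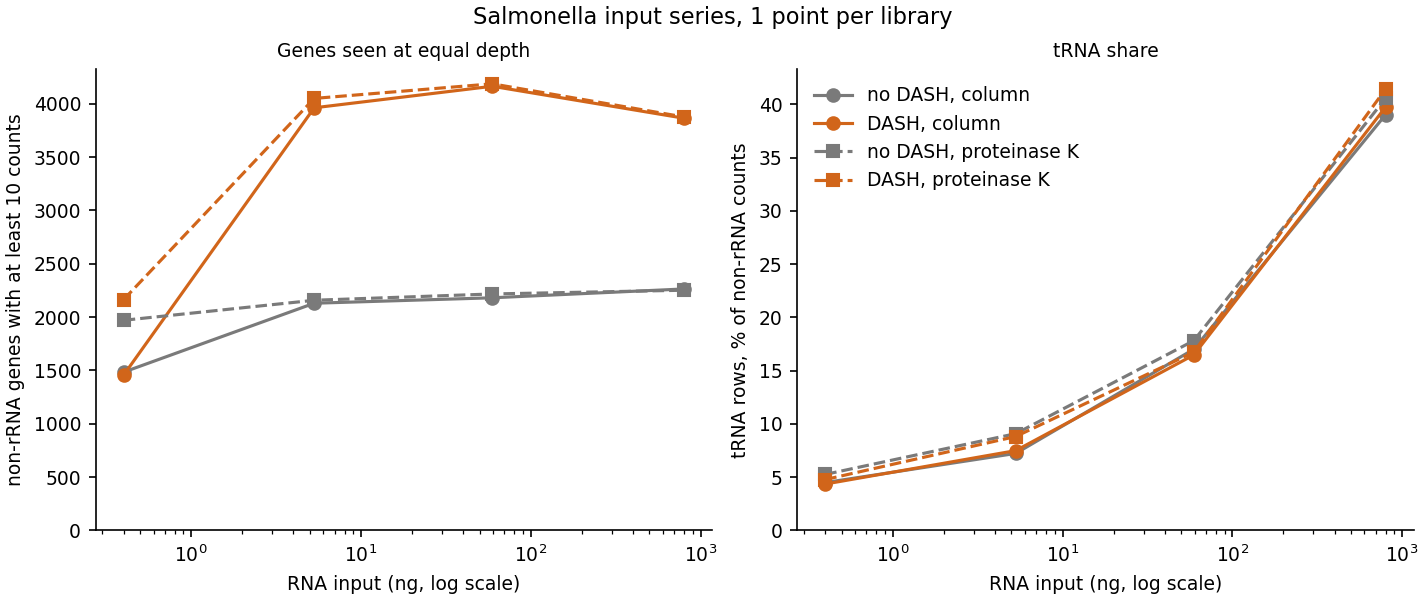
Genes seen (left y axis, number of non-rRNA genes with at least 10 counts after thinning to equal depth) and tRNA share (right y axis, percent of non-rRNA counts) against RNA input (x axis, ng, log scale) in the 16 libraries of the Salmonella input series, 1 point per library, with lines joining libraries of the same treatment. From 5.3 ng upward DASH libraries show 3865 to 4188 genes against 2130 to 2264 without DASH, and the tRNA share lies between 4.35% and 5.25% at 0.4 ng and between 39.0% and 41.5% at 800.3 ng in both.

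Whether DASH altered the remaining transcriptome was asked gene by gene in the 8 pairs. No gene of 4161 passed the threshold. The 6 housekeeping noncoding RNAs lay near 0: 6S RNA, a regulator of RNA polymerase, at 0.09 ± 0.05 (SE), the ribosome rescue RNA tmRNA at 0.09 ± 0.07, the RNase P RNA RnpB at 0.12 ± 0.10, the signal recognition particle RNA 4.5S at 0.07 ± 0.03, and CsrB and CsrC, which bind the regulator CsrA, at 0.07 ± 0.045 and 0.09 ± 0.06, all with adjusted p = 1. The sRNA ArcZ lay at -0.89 ± 0.44 and below 0 in 8 of 8 pairs, and invB, a chaperone of invasion effectors, at 0.23 ± 0.10 and above 0 in 8 of 8, both with adjusted p = 1. Of the 11 lists, none passed. Ribosomal proteins came nearest (51 measured, median 0.14, limma camera adjusted p = 0.0555), followed by outer membrane proteins (14 measured, 0.10, adjusted p = 0.0847) and housekeeping RNAs (all 6 above 0, 0.09, adjusted p = 0.0847). With the tRNA genes left out of the fit these 3 passed (adjusted p = 0.0124, 0.0252 and 0.0169). With an estimated correlation, run with the tRNA genes in, all 3 were at an adjusted p = 0.609. The median was -0.20 in SPI-2, -0.08 in Hfq- and ProQ-associated sRNAs, 0.09 in SPI-1, 0.06 in heat shock genes, 0.01 in tRNAs, -0.01 in rRNA operon tRNAs, and 0.00 in flagella and in ATP synthase. At an unadjusted p under 0.05, edgeR counted 18 genes, and DESeq2 called 0 with 52 unadjusted. In simulated data the same test recovered 22% of genes changed by a log2 of 2.

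The 0.4 ng libraries listed counts for far fewer genes than the others. Without them, a choice made after the data were seen, 9 genes fell and 0 rose of 4106. Of the 9, 4 were StyR-44 genes, short RNAs from the rRNA operon next to 23S rRNA, with StyR-44e at -0.28 ± 0.05 (SE) and StyR-44c at -0.27 ± 0.04. The other 5 were tRNAs, with tRNA-Asp@304258 and tRNA-Gln@737540 at -0.27, tRNA-Asp@294819 at -0.15, and tRNA-Met@3162526 and tRNA-Met@3162632 at -0.30 and -0.28. StyR-44 copies share reads with each other. In the same fit rRNA operon tRNAs (1 fell, median -0.02) lay below other genes (camera adjusted p = 4.57e-06, adjusted p = 0.277 with an estimated correlation), and tRNAs (5 fell of 85) had a median of 0.01 and a mean of -0.01 with the test downward (2.83e-04, adjusted p = 0.640 with an estimated correlation). Hfq- and ProQ-associated sRNAs (0 called, 1 rose and 5 fell adjusted over the list alone, median -0.07) lay below other genes as well (adjusted p = 0.0187, adjusted p = 0.484 with an estimated correlation). Ribosomal proteins (median 0.04, adjusted p = 0.0364) and heat shock genes (0.03, adjusted p = 0.0426) lay above, each at an adjusted p = 0.277 with an estimated correlation. With the 800.3 and 59.3 ng libraries alone, 33 genes were called, 2 up and 31 down.

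**Figure D3:**
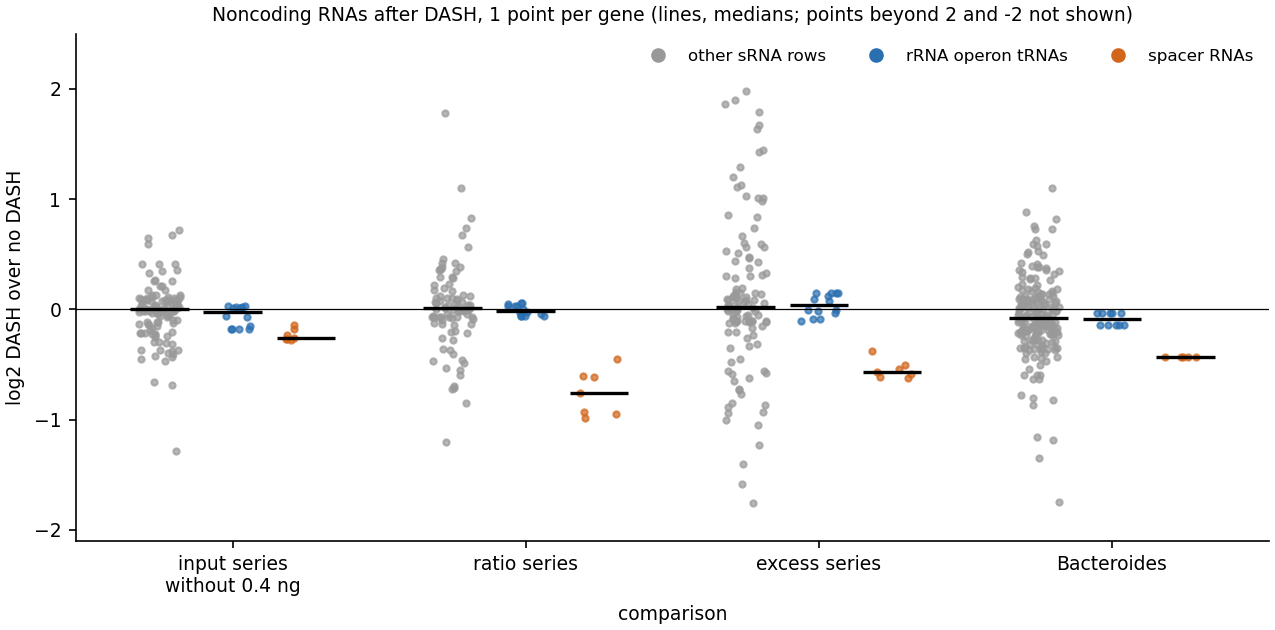
Change of noncoding RNAs after DASH (y axis, log2 of DASH over no DASH) in 4 comparisons (x axis), 1 point per gene, with black lines at the medians of the rRNA operon spacer RNAs (StyR-44 in Salmonella, 5 BTnc genes in Bacteroides), the rRNA operon tRNAs and the other sRNAs; points beyond 2 are left out. Spacer RNA medians lie at -0.26, -0.76, -0.57 and -0.43, while those of the other sRNAs lie at -0.00, 0.01, 0.02 and -0.08. The first comparison leaves out the 0.4 ng libraries, a choice made after the data were seen, and with all 8 pairs, not shown, the medians were -0.08 and -0.03. The Bacteroides values average the NEB and Takara kits, between which the effect on the spacer RNAs differed with DESeq2.

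The DASH effect itself was compared between clean-ups and across inputs. Between clean-ups 0 of 4161 genes differed (edgeR, 11 unadjusted; DESeq2 0 with 30). None of the 11 lists passed, with tRNAs at a median of -0.11 (camera adjusted p = 0.0709) and housekeeping RNAs at -0.06 (adjusted p = 0.920). With RNA input edgeR found 0 of 4161 genes (377 unadjusted), and DESeq2 called 142, 89 up and 53 down. The 6 housekeeping RNAs had negative coefficients, with tmRNA at -0.14 ± 0.03 (SE) and 6S RNA at -0.10 ± 0.03 (adjusted p = 0.525 for both), and 2 of them fell adjusted over the list alone. Among tRNAs 4 rose and 7 fell adjusted over the list alone, but the list did not pass (median -0.04, camera adjusted p = 0.648). Without the 0.4 ng libraries, a choice made after the data were seen, tRNA-Pro@4162809 rose by 0.23 and tRNA-Met@3162526 and tRNA-Met@3162632 fell by 0.20 per 10-fold input, and the tRNA list lay above other genes (median 0.04, camera adjusted p = 0.00136, adjusted p = 0.657 with an estimated correlation).

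Proteinase K and column clean-up were also compared for the composition of the libraries. Of 86 tRNAs, 69 were above 0 with a median log2 of 0.16 in proteinase K over column, while 0 passed on their own. The list lay above other genes (camera adjusted p = 1.83e-05, adjusted p = 0.305 with an estimated correlation). Of 14 rRNA operon tRNAs, 11 were above 0 (median 0.13, camera adjusted p = 0.0248, adjusted p = 0.305 with an estimated correlation), and 7 rose adjusted over the list alone. tRNA-Leu@4831447, at 0.28 ± 0.06 (SE), and tRNA-Thr@4381377, at 0.21 ± 0.05, were among the smallest p-values of the list (adjusted p = 1). SPI-1 (median -0.01), heat shock genes (-0.08) and Hfq- and ProQ-associated sRNAs (-0.14) came nearest among the other lists (camera adjusted p = 0.0517 for each). Ribosomal proteins had a median of 0.08, flagella 0.06, outer membrane proteins, ATP synthase and housekeeping RNAs 0.02, and SPI-2 0.24, with adjusted p from 0.588 to 0.971. The median of all genes was 0.11. No gene of 4161 passed (edgeR, 37 unadjusted; DESeq2 0 with 34), and without the 0.4 ng libraries, a choice made after the data were seen, tRNA-Sec@3969890 rose by 0.44 ± 0.04 (SE, adjusted p = 5.1e-04). In that fit tRNAs (59 of 85 rose adjusted over the list alone, adjusted p = 0.0976 with an estimated correlation), rRNA operon tRNAs (14 of 14, adjusted p = 0.107) and housekeeping RNAs (2 of 6, adjusted p = 0.0976) lay above other genes with camera. SPI-1 lay below them (0 rose and 2 fell of 33 adjusted over the list alone, camera adjusted p = 1.16e-06, adjusted p = 0.0624 with an estimated correlation).

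The trend with RNA input asked how the amount of RNA affected the composition of the Salmonella libraries. tRNAs took 4.87% of non-rRNA counts at 0.4 ng and 39.8% at 800.3 ng without DASH, and 4.56% and 40.6% with DASH (means of 2 libraries), while coding genes went from 81.5% to 48.2% without DASH. Of 85 measured tRNAs 84 rose and 0 fell, with a median log2 of 1.41 per 10-fold input. tRNA-Pro@2328470 rose by 2.75 ± 0.17 (SE), tRNA-Arg@4162453 by 2.67 ± 0.22 and tRNA-Val@1458502 by 0.69 ± 0.02. All 14 rRNA operon tRNAs rose (median 1.30), tRNA-Asp@4126828 by 1.41 ± 0.04. The tRNA and operon tRNA lists lay above other genes with camera (adjusted p = 4.41e-154 and 8.61e-51) and with an estimated correlation (adjusted p = 9.61e-04 for both). Near-identical tRNA copies share reads.

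The trend called 265 genes of 3874, 174 up and 91 down, at 16 libraries from 4 RNA inputs. The median of all genes was 0.19 per 10-fold input with TMM and 0.00 with library sizes alone, so that small slopes are read relative to it, and under library sizes the split was 112 up and 259 down. Among the largest rises outside tRNAs were the short RNAs STnc1210 (2.96 ± 0.45 SE) and Msr (2.68 ± 0.23) and the coding gene SL1344_3010 (2.33 ± 0.42), each up in 4 of 4 series of treatment and clean-up. Among the largest falls were aadA, an aminoglycoside resistance gene (-1.34 ± 0.25), speE of spermidine synthesis (-0.69 ± 0.16), aroC of aromatic amino acid synthesis (-0.50 ± 0.15), the invasion effector gene sopE (-0.49 ± 0.05) and manY of mannose uptake (-0.48 ± 0.06), each down in 4 of 4 series. Hfq- and ProQ-associated sRNAs had 9 that rose and 1 that fell of 27 (12 and 1 adjusted over the list alone; median 0.54, camera adjusted p = 0.0123, adjusted p = 0.0562 with an estimated correlation). MicA (2.53 ± 0.53) and MgrR (1.70 ± 0.27), regulators of envelope genes, and ChiX (0.51 ± 0.02), a regulator of chitoporin, rose, and GlmY, a regulator of amino sugar synthesis, fell (-0.51 ± 0.08). Outer membrane proteins lay below other genes, with 0 that rose and 5 that fell of 14, also adjusted over the list alone (median -0.08, camera adjusted p = 8.82e-06, adjusted p = 0.0367 with an estimated correlation). ompC (-0.24 ± 0.03), ompA (-0.21 ± 0.03) and ompD (-0.13 ± 0.02) were examples.

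Lists near the median of all genes had small slopes whose sign depended on the scaling. Ribosomal proteins (2 rose and 3 fell of 49, and 3 and 5 adjusted over the list alone) had a median of 0.01 and a mean of 0.05, yet lay below other genes (camera adjusted p = 1.25e-04, adjusted p = 0.140 with an estimated correlation), with rplV at -0.23 ± 0.04 (SE) and rplX at 0.29 ± 0.08. SPI-1 (5 rose and 5 fell of 33, and 10 and 5 adjusted over the list alone) had a median of 0.06 and also lay below other genes (camera adjusted p = 0.0177, adjusted p = 0.224 with an estimated correlation), with prgH of the secretion needle base at -0.26 ± 0.03. With library sizes alone the medians turned to -0.16 for ribosomal proteins (0 rose, 16 fell), -0.13 for SPI-1 (0 rose, 9 fell), -0.13 for ATP synthase (0 rose, 4 fell), -0.10 for flagella (0 rose, 8 fell), -0.15 for heat shock genes (0 rose, 5 fell) and -0.13 for housekeeping RNAs (1 rose, 3 fell). With TMM those of the last 4 were 0.03 (3 rose, 1 fell), 0.07 (1 rose, 1 fell of 52), 0.02 (2 rose, 0 fell of 14; 2 and 1 adjusted over the list alone) and 0.04 (3 rose, 3 fell), and none of them passed the list test (camera adjusted p = 0.267, 0.147, 0.0826 and 0.160). RnpB rose (0.43 ± 0.04) and 4.5S (-0.31 ± 0.04), CsrC (-0.26 ± 0.03) and CsrB (-0.09 ± 0.02) fell, while 6S RNA (0.18) and tmRNA (0.17) lay at the median of all genes and were at 0.01 and 0.00 with library sizes. ATP synthase had atpC at 0.32 and atpE at -0.19, heat shock genes clpX at 0.31 and groES at 0.10, and flagella fliC at -0.13 and cheW at 0.27. In SPI-2, 1 of 14 measured genes rose (ssaU; median 0.59, camera adjusted p = 0.258), and without the 0.4 ng libraries the median was -0.06, with 1 that rose and 1 that fell of 15 (adjusted p = 0.889). DESeq2 called 855 genes, 675 up and 180 down, and the fit with tRNA genes left out called 161. Without the 0.4 ng libraries, a choice made after the data were seen, 798 genes were called, 412 up and 386 down, including 242 of the 265 in the same direction, and the outer membrane list was at an adjusted p of 0.0084 (adjusted p = 0.152 with an estimated correlation).

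**Figure D4:**
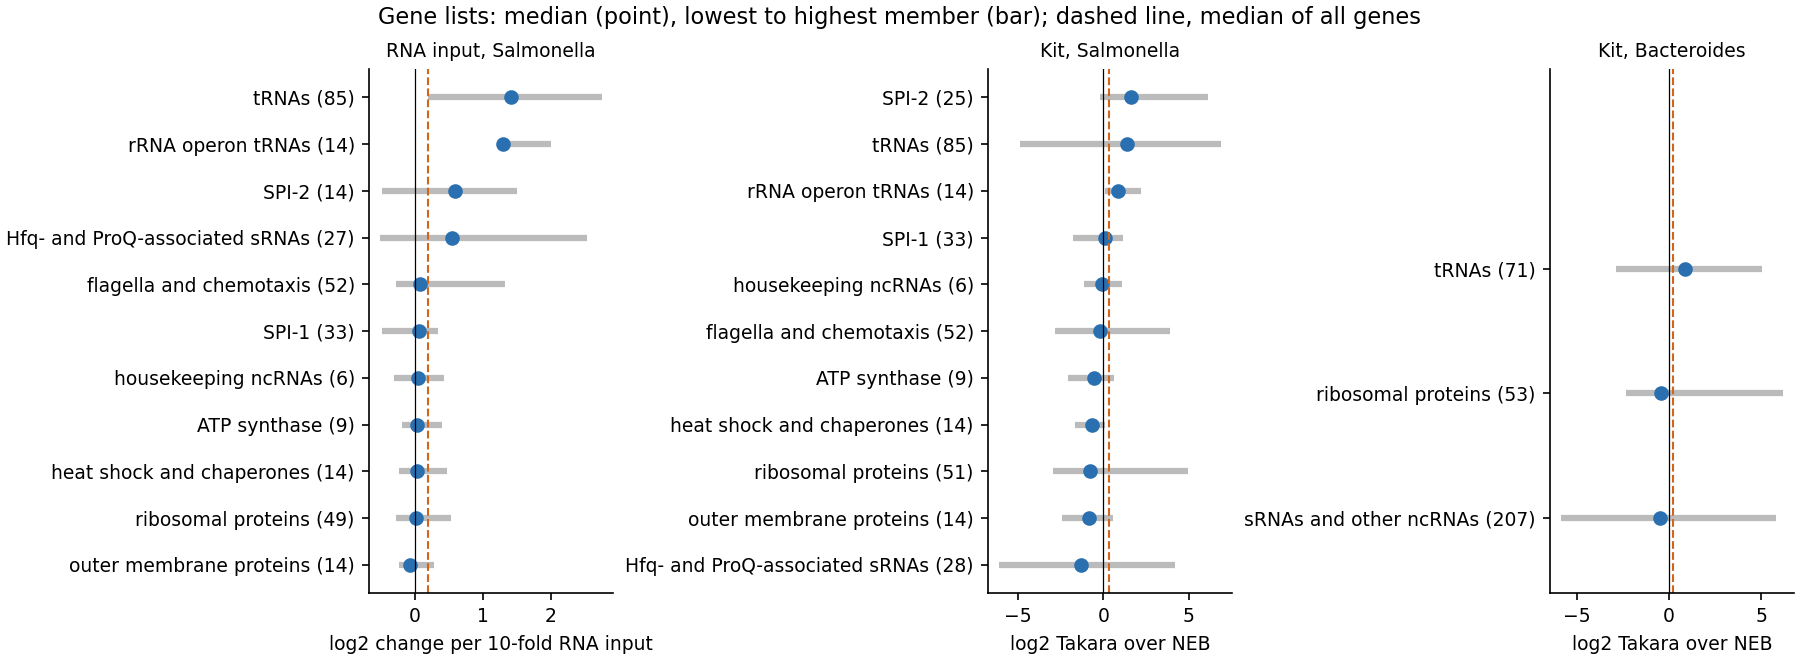
Median log2 change of each gene list (point) and its lowest to highest member (grey bar) per 10-fold RNA input in Salmonella and in Takara over NEB libraries of Salmonella and of Bacteroides (x axis, log2), with the number of measured genes in brackets, a black line at 0 and a dashed line at the median of all genes (0.19, 0.35 and 0.23). tRNAs lie at 1.41, 1.41 and 0.90, above the dashed line in each panel; with library sizes alone 6 medians of the left panel turn negative (ribosomal proteins, SPI-1, ATP synthase, flagella, heat shock, housekeeping RNAs) and that of the housekeeping RNAs turns positive in the middle panel.

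The ratio series asked which excess of Cas9 and sgRNA depleted rRNA best, with 1 library per condition and 95% Clopper-Pearson intervals at most 0.092 percentage points wide. rRNA took 95.9% of counts without DASH. At 1:100:1000 it took 84.0%, a log2 change of -2.14 (4.41-fold) and the lowest share among the 7 ratios. Shares were 90.4% at 1:1000:1000, 90.8% at 1:10:10, 91.9% at 1:100:100 and 91.9% at 1:10:100. With less sgRNA than Cas9, at 1:1000:100 and 1:100:10, they were 95.6% and 95.7% (log2 -0.10 and -0.06). The mean share was 95.6% at 0.1 sgRNA per Cas9, 91.0% at 1 and 88.0% at 10. The rRNA ratio was lower at higher sgRNA per Cas9 (r = -0.85, exact permutation p = 0.0381, adjusted p = 0.114 over 3 relations, rho = -0.66, p = 0.152, n = 7), so the relation failed the correction. The 4 libraries at 0.1 and 10 sgRNA per Cas9 lie equally far from the median ratio of 1: without the 2 at 10 r was -0.99 (exact permutation p = 0.1, adjusted p = 0.3 over 3 relations, n = 5), and without the 2 at 0.1, a choice made after the data were seen, r was -0.47 (exact permutation p = 0.5, n = 5). With Cas9 alone r was 0.24 (exact permutation p = 0.667, rho = 0, p = 1, n = 7, r = 0.28 without the 2 at 10 sgRNA per Cas9 and -0.26 without the 2 at 0.1), and with sgRNA alone r was -0.61 (exact permutation p = 0.152, adjusted p = 0.229, rho = -0.66, p = 0.152, n = 7, r = -0.37 and -0.56 without them).

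In the same 8 libraries 0 of 2782 genes passed between the 7 DASH libraries and the single undepleted one (edgeR, 124 unadjusted; DESeq2 0 with 37). The genes with the smallest p included StyR-44b (-0.76 ± 0.18 SE) and StyR-44a (-0.99 ± 0.25, adjusted p = 0.36 for both), named after their values were seen. With no filter or without tRNA genes 4 StyR-44 copies were called, and with thinned counts 5 genes were called. Leaving out the 1:1000:100 or the 1:100:10 library also gave 4. All these calls rest on the single undepleted library, whose own spread is not known. With rRNA genes kept in the fit, they had a median log2 of -0.83 and did not pass either. The rRNA ratio itself changed by a log2 between -0.06 and -2.14 in single DASH libraries, least in those with less sgRNA than Cas9. The gene test pools these libraries, so it could miss a change of that size that differs between conditions. How it treats an even change cannot be read from the rRNA genes. None of the 11 lists passed, with tRNAs nearest (83 measured, median 0.04, camera adjusted p = 0.0727), and SPI-1 had only 3 of 33 genes measured. The other medians were 0.12 for ATP synthase, 0.08 for SPI-2, 0.03 for housekeeping RNAs, 0.01 for outer membrane proteins, -0.00 for flagella, -0.01 for ribosomal proteins, -0.01 for rRNA operon tRNAs, -0.02 for heat shock genes and -0.07 for Hfq- and ProQ-associated sRNAs.

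The excess series asked whether more Cas9, at 10 sgRNA per Cas9, depleted more rRNA. In Salmonella NEB libraries rRNA took 95.5% without DASH and 60.8%, 45.0% and 43.0% at 1:100:1000, 1:1000:10000 and 1:3500:35000 (log2 -3.78, -4.71 and -4.82). In Bacteroides NEB libraries it took 77.5% without DASH and 20.0%, 14.595% and 11.03% (log2 -3.79, -4.34 and -4.80, the last 27.8-fold). In Bacteroides Takara libraries it took 79.7% and then 26.1%, 27.7% and 20.4% (log2 -3.48, -3.36 and -3.94, the last 15.3-fold). Over the 9 DASH libraries the rRNA ratio fell by 0.53 log2 per 10-fold Cas9 (exact two-sided permutation within 3 series, p = 0.0185), with slopes of -0.71, -0.64 and -0.25. sgRNA rose in the same proportion as Cas9, so the slope belongs to both together and cannot be assigned to Cas9 alone. Without the Salmonella NEB series the slope was -0.44 and without the Bacteroides NEB series -0.48 (exact permutation p = 0.111 for each). Single pairs, with no test, were a Takara pair of Salmonella at 1:3500:35000, with 96.0% and 57.8% (log2 -4.14), and the preincubation pair at 1:100:1000, with 94.3% and 76.3% (log2 -2.37). 5S rRNA was the class depleted least in the Takara libraries, at -2.61 against -4.08 for 23S in Salmonella and at -2.64, -2.47 and -3.23 against -3.56, -3.44 and -3.99 in Bacteroides.

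In the Salmonella excess series 0 of 4634 genes passed between 4 DASH and 2 undepleted libraries (edgeR, 53 unadjusted; DESeq2 0 with 152). tmRNA lay at 0.10 ± 0.05 (SE) and 6S RNA at 0.12 ± 0.08. Outer membrane proteins (14 measured, median 0.10) and ribosomal proteins (51 measured, median 0.07) lay above other genes (camera adjusted p = 0.0233 for both), as did SPI-1 (33 measured, median 0.06, adjusted p = 0.0392), each at an adjusted p = 0.610 with an estimated correlation, and 0 of their genes were called. The other 8 lists did not pass: flagella (median 0.06), heat shock genes (0.06), housekeeping RNAs (0.08), ATP synthase (0.07), Hfq- and ProQ-associated sRNAs (0.06), rRNA operon tRNAs (0.04), tRNAs (-0.01), and SPI-2 (median 0.05, mean -0.20, test downward), with camera adjusted p from 0.0567 to 0.822.

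The kits, which copy RNA in different ways, were compared too. In the same 6 Salmonella libraries Takara over NEB called 835 of 4634 genes, 396 up and 439 down, while library sizes alone gave 441 and 350, thinned counts 559 and 449 and DESeq2 616 and 593. Of 85 tRNAs 53 rose and 12 fell (55 and 12 adjusted over the list alone; median 1.41, camera adjusted p = 6.14e-33, adjusted p = 0.183 with an estimated correlation), with tRNA-Gln@737863 at 6.19 ± 0.18 (SE), tRNA-Pro@3841737 at 5.68 ± 0.15 and tRNA-Val@1458502 at -4.86 ± 0.15. Of 14 rRNA operon tRNAs 9 rose (10 adjusted over the list alone; median 0.85, adjusted p = 9.29e-09, adjusted p = 0.216 with an estimated correlation). Of 28 Hfq- and ProQ-associated sRNAs 3 rose and 11 fell, also adjusted over the list alone (median -1.29, adjusted p = 9.24e-07, adjusted p = 0.157 with an estimated correlation), ChiX by -3.77 ± 0.10 and GcvB, a regulator of amino acid uptake, by -3.11 ± 0.19. Ribosomal proteins had 4 that rose and 28 that fell of 51 (5 and 29 adjusted over the list alone; median -0.75, adjusted p = 5e-15, adjusted p = 0.105 with an estimated correlation), with rplV at -2.30 ± 0.12. Outer membrane proteins had 0 and 8 of 14 (1 and 11 adjusted over the list alone; median -0.82, adjusted p = 7.19e-09, adjusted p = 0.157 with an estimated correlation), with the lipoprotein gene lppA at -2.39 ± 0.09.

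Heat shock genes had 0 that rose and 9 that fell of 14 in Takara over NEB (0 and 10 adjusted over the list alone; median -0.63, camera adjusted p = 2.9e-04, adjusted p = 0.183 with an estimated correlation), with groES at -1.03 ± 0.10 (SE). ATP synthase had 1 and 5 of 9 (2 and 7 adjusted over the list alone; median -0.54, adjusted p = 0.00187, adjusted p = 0.157 with an estimated correlation), with atpE at -2.05 ± 0.13. Flagella and chemotaxis had 3 and 12 of 52 (4 and 13 adjusted over the list alone; median -0.21, adjusted p = 0.0271, adjusted p = 0.304 with an estimated correlation), with the chemoreceptor gene tar at -1.28 ± 0.12. SPI-1 had 8 and 7 of 33 (10 and 9 adjusted over the list alone; median 0.09, mean -0.03, test downward, adjusted p = 0.566). Of the 6 housekeeping RNAs 2 rose and 2 fell (median -0.08, and 0.08 with library sizes alone, adjusted p = 0.741), with CsrB at 1.10 ± 0.09 and 6S RNA at -1.15 ± 0.09. SPI-2 had 1 and 0 of 25 (sseC, 2.90 ± 0.59; median 1.64, adjusted p = 0.157). The median of all genes was 0.35, and 0.51 with library sizes alone. DESeq2 called 1209 genes. The count fell to 405 without the NEB undepleted library (187 up, 218 down), to 440 without the Takara undepleted library (177 up, 263 down) and to 336 without the Takara DASH library (107 up, 229 down). RNA input differed with the kit, and the fit does not separate them. Whether the reads of both kits were counted in the same way is not stated, and a difference in counting would enter these values. The genes named here were chosen after their values were seen.

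In Bacteroides, 0 of 4923 genes passed between 6 DASH and 2 undepleted libraries (edgeR, 155 unadjusted). DESeq2 called 5 with 160 unadjusted, the rRNA operon RNAs BTnc_057, BTnc_091, BTnc_132, BTnc_150 and BTnc_217, which lay at -0.44 to -0.43 with an SE of 0.10 in edgeR and share reads. Leaving out the Takara undepleted library also gave these 5 in edgeR. The fit averages both kits, and the DASH effect on these 5 lay higher in Takara than in NEB with DESeq2, as given below. Of 71 tRNAs 69 lay below 0 (median -0.16, camera adjusted p = 1.41e-22, adjusted p = 0.178 with an estimated correlation), with tRNA-Met@4890894 at -0.33 ± 0.10 (SE). Of 53 ribosomal proteins 50 lay above 0 (median 0.07, adjusted p = 2.04e-12, adjusted p = 0.111 with an estimated correlation), with rpsQ at 0.15 ± 0.04. Noncoding RNAs (207 measured) had a median of -0.09 and a mean of 0.00 with the test downward (p = 0.00108, adjusted p = 0.279 with an estimated correlation). None of these genes was called, also adjusted over the list alone.

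Takara and NEB libraries of Bacteroides differed in 2740 of 4923 genes, 1483 up and 1257 down in Takara. Of 71 tRNAs 52 rose and 15 fell, also adjusted over the list alone (median 0.90, camera adjusted p = 1.85e-31, adjusted p = 0.105 with an estimated correlation), with 5 tRNA-Ala copies that share reads at 4.46 ± 0.06 (SE). Of 207 noncoding RNAs 47 rose and 98 fell (47 and 100 adjusted over the list alone; median -0.48, adjusted p = 5.2e-07, adjusted p = 0.105 with an estimated correlation). BTnc_048 (-5.83 ± 0.48), BTnc_136 (-5.21 ± 0.11), BTnc_104 (-4.70 ± 0.24) and BTnc_198 (-4.21 ± 0.09) were among the largest falls. Of 53 ribosomal proteins 15 rose and 35 fell (16 and 36 adjusted over the list alone; median -0.43, adjusted p = 1.49e-09, adjusted p = 0.105 with an estimated correlation), with rplX at 2.10 ± 0.04, rplQ at -1.97 ± 0.04 and rpsL at -1.83 ± 0.04. With library sizes alone the median of all genes moved from 0.23 to 0.60, the calls to 2248 up and 752 down, and ribosomal proteins to 22 up and 26 down.

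The largest rises in Takara were coding genes with almost no NEB reads. N-acetylmuramoyl alanine amidase NP_813354.1, a cell wall enzyme, had 20811 counts in the 4 Takara libraries and 6 in the 4 NEB libraries (log2 11.30 ± 0.33 SE). The hypothetical protein NP_811908.1 had 1617 and 0 counts, at least 547-fold higher against a floor of 3 counts over the 4 NEB libraries. By the same floor the hypothetical protein NP_809196.1 was at least 476-fold, the transposase NP_810842.1 at least 268-fold and the conjugate transposon protein NP_811203.1 at least 190-fold higher. The outer membrane efflux protein NP_810381.1 had 2179 and 3 counts, a ratio of 737 (95% counting interval 252 to 3578.5). Of the 1483 genes called up, 115 were at 0 in the NEB libraries, and of the 1257 called down 0 were at 0 in Takara. In Salmonella, 30 of the 396 genes called up were at 0 in NEB. Bacteroides RNA input differed with the kit too (1 ng against 4.5 to 6.7 ng), and a difference in how reads were counted would enter these values as well.

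The DASH effect was compared between kits in Bacteroides. 0 of 5005 genes differed with edgeR (248 unadjusted), and DESeq2 called 7, all up, which were the 5 BTnc RNAs above, NP_812019.1 and NP_813354.1. The effect lay higher in Takara, relative to other genes, for tRNAs with 59 of 71 above 0 (median 0.22, limma camera adjusted p = 6.87e-08), and for noncoding RNAs, with 141 of 222 above 0 (median 0.14, mean -0.02, adjusted p = 0.00879). Both had an adjusted p = 0.552 with an estimated correlation. Each kit had 1 undepleted library, so a shift in either enters all genes of the interaction. NP_813354.1 also had only 6 counts over all NEB libraries, so its DASH effect in NEB rests on few reads. BTnc_091 lay at 0.57 ± 0.07 (SE, adjusted p = 0.057), and 5 noncoding RNAs rose adjusted over the list alone. Ribosomal proteins had a median of 0.00 (camera adjusted p = 0.980).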

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

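The tests of other short RNAs, of the 9 genes in the excess series, of 23S fragments, of tRNA copies in Bacteroides, of the 0.4 ng libraries, of the scalings and of the splits for DASH, proteinase K and the DASH effect by clean-up were chosen only after the result was seen, as were the subset without the 0.4 ng libraries and the limit of the Bacteroides kit splits to those that part all pairs.

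A single library lay far from the other 3 of its group in 2 of 40 tests with Dixon's ratio (4 groups of libraries with 10 measures each), beyond its 95% critical value, and chance flags about 1 in 20 groups. In the proteinase K DASH libraries of the input series, sRNAs took 11.65% of non-rRNA counts at 800.3 ng and 14.669 to 14.786% at the other inputs. In the proteinase K libraries without DASH, 2817 genes had a count at 0.4 ng and 4303 to 4596 at the other inputs. Both libraries were at an end of the input range, which is itself part of the design. In Bacteroides the DASH effect lay higher in Takara than in NEB for noncoding RNAs (median log2 0.1397) and for tRNAs (0.2155), tested as an interaction with camera. Each kit had 1 undepleted library, and a shift in either moves the tRNAs together (estimated correlation 0.731), so that the difference rests on single libraries. Neither list passed with an estimated correlation (adjusted p = 0.552 for both), and 0 single genes passed with edgeR (248 at an unadjusted p under 0.05; DESeq2 called 7).

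The rRNA operon spacer RNAs, StyR-44 in Salmonella and BTnc_057 with its 4 copies in Bacteroides, lay below other sRNAs after DASH, a pattern defined after the values of all 4 DASH comparisons were seen and not met in the input series with all 8 pairs, where they lay 0.049 below (median absolute deviation of the other sRNAs 0.42). Without the 0.4 ng libraries 9 genes were called and at most 5 in the other splits of 32 (1 as large, the real one), but that subset was chosen after its values were seen and 5 of the 9 are tRNAs, so this does not exclude chance for the spacer RNAs. The other sRNAs, of all lengths, were not chosen for the pattern. Their medians were -0.00 in the input series without 0.4 ng, 0.01 and 0.02 in the ratio and Salmonella excess series and -0.08 in Bacteroides. As a group they stayed near 0, so a general loss of sRNAs was not seen in these fits. They lay above the spacer medians by more than their median absolute deviation in 4 of 4 comparisons. This restates how the pattern was defined, so it cannot decide on an equal loss of short noncoding RNAs. In the input series without 0.4 ng, 5 Hfq- and ProQ-associated sRNAs fell adjusted over the list alone (camera adjusted p = 0.0187, adjusted p = 0.484 with an estimated correlation). The Bacteroides fit averages 2 kits, and the DASH effect on its spacer RNAs lay higher in Takara with DESeq2. Cleavage of fragments running from the spacer into 23S rRNA cannot be told apart from other causes, since the relation of spacer share and rRNA ratio over 7 ratio libraries (r = 0.873, exact permutation p = 0.0169, rho = 0.54, p = 0.236) rests on the 2 with less sgRNA than Cas9 (shares 0.410 and 0.412%, others 0.208 to 0.253%), without which r was 0.36. The share in the undepleted library was 0.463%. Those 2 libraries also went through the DASH steps, with rRNA changes of only log2 -0.10 and -0.06, and their shares lay nearer to the undepleted one. Each condition had 1 library, so these values do not decide between the causes. Only 5 of the 9 genes were below 0 in the excess series, 4 StyR-44 genes and tRNA-Gln@737540, so a difference of the input series alone stays open for the other 4 tRNAs, and no biological explanation was tested.

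The rise of tRNAs with RNA input did not come from the 0.4 ng libraries alone, since the median slope without them was 1.6551. It did not come from the scaling alone either, since the lowest median over the scalings was 1.2497. Recovery of short RNAs at higher input is a candidate explanation, since 78 sRNAs under 150 nt had a median slope 0.534 above that of 30 longer ones (permutation p = 0.0092, bootstrap interval 0.245 to 0.840, which was added after the first value was seen). Both the permutation and the interval treat sRNAs measured in the same libraries as independent units, which they may not be. The design gives no biological difference between inputs, so no biological explanation was tested.

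The tRNA list lay higher in Takara libraries of both species with camera, but not with an estimated correlation (adjusted p = 0.183 in Salmonella and 0.105 in Bacteroides). Of the 8 splits of the Bacteroides libraries that part all 4 pairs only the real one (1) called as many genes, with 2740 against 0 in the highest other, and 8 splits are too few for a share under 0.05. Lower RNA input cannot be separated from the kit, since input differed with it. In Salmonella the kit difference had a Spearman rho of 0.1605 with the slope per 10-fold RNA input across 3950 genes, which are not independent replicates. That slope came from NEB libraries without the 0.4 ng ones, and the 1 ng of the Takara libraries lies below the inputs left. tRNAs rose with input in NEB libraries, also with 0.4 ng kept, so lower input acting as it did there would lower them. Whether input acts in the same way in Takara libraries was not tested. Reads divided between copies stay open as a cause in both species. A near-identical copy here means another tRNA within 5% of the counts in every NEB library. Sequences were not compared. In Salmonella 42 tRNAs without such a copy had a median of 2.2868 (median absolute deviation 1.80, 31 rose and 6 fell), against 0.47 in the 43 with one. In Bacteroides the median of 55 without one was 0.997 (median absolute deviation 1.49, 42 rose and 9 fell), against 0.31 in the 16 with one. Copies with unequal counts fall among those without one. The grouping also uses the NEB counts that enter the kit difference, so these values cannot decide. Capture of short RNAs by the kit cannot be told apart from other causes in either species, since short minus long RNAs gave -0.565 in Salmonella (permutation p = 0.117, bootstrap interval -1.47 to 0.173) and 0.209 in Bacteroides (p = 0.502, -0.333 to 0.944), and no biological explanation was tested.

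Other splits were also run for 3 comparisons with 0 genes called by edgeR. For DASH against no DASH (18 at an unadjusted p under 0.05; DESeq2 0) and for proteinase K against column (37; DESeq2 0), 100 splits were run each, and for the DASH effect by clean-up (11; DESeq2 0) 8. The highest other split called 0 in each, but with a real value of 0 any split gives as many, so these splits say nothing about chance.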

How the results depend on the processing

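The tests without the 0.4 ng libraries, with the 800.3 and 59.3 ng libraries alone, and without the libraries at the lowest sgRNA to Cas9 ratio, were chosen only after the result was seen. Of the values given in the report, 110 comparisons with an alternative kept direction and side of the threshold, or their size for values with no test, and 47 did not, as did 111 and 6 when a library or pair was left out. The fall of rRNA in the input series was -4.00 to -3.81 with a pair left out. Its relation with RNA input was -0.6819 without the 2 farthest pairs and 0.9034 without 0.4 ng, and the cause was not tested. The relation of the rRNA ratio with Cas9 in the ratio series turned to -0.2577 without the 2 libraries at the lowest sgRNA to Cas9 ratio. The Cas9 slope of the excess series, where sgRNA rose with Cas9, was -0.4432 without Salmonella NEB and -0.476 without Bacteroides NEB, with fewer libraries. With tRNA genes left out of the other counts, the single pairs had -2.365 for preincubation and -4.126 for Salmonella Takara, and the means of 3 DASH libraries against the same undepleted library were -4.451 for Salmonella NEB, -4.338 for Bacteroides NEB and -3.609 for Bacteroides Takara. With 16S and 23S only, the Salmonella Takara pair had -4.157 and the mean of 3 for Bacteroides Takara was -3.674. With rRNA genes kept, 22 genes were called for DASH in the input series, 22 in the Salmonella excess series and 15 in Bacteroides, all of them rRNA genes. In the ratio series the kept rRNA genes had a median log2 of -0.83 and did not pass. With DESeq2, 855 genes were called for the trend, 142 for the DASH effect by RNA input, 5 for DASH in Bacteroides and 7 for its interaction with kit. Without 0.4 ng the counts were 9 for DASH, 1 for proteinase K, 798 for the trend and 3 for the DASH effect by RNA input, and with the 800.3 and 59.3 ng libraries alone 33 for DASH and 28 for proteinase K. Leaving out tRNA genes gave 161 for the trend and 4 for the ratio series, which had 4 with no filter and 5 with thinned counts. With a library or pair left out, counts were 0 to 4 in the ratio series, 0 to 5 for DASH in Bacteroides, 336 to 960 for the Salmonella kits, 204 to 294 for the trend and 2193 to 2479 for the Bacteroides kits, and 0 to 0 in the other 6 comparisons. The cause of these count changes was not tested.

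Lists called with an estimated correlation numbered 0 for proteinase K (2 with the preset one), 3 for the trend (6), 0 for DASH (3) and 0 for kit (8) in the Salmonella excess series, and 0 for DASH (3), kit (3) and interaction (2) in Bacteroides. With fry they were 0 for proteinase K, 0 for DASH in the Salmonella excess series, 1 for DASH in Bacteroides and 0 for the interaction. With tRNA genes left out they were 3 for DASH in the input series, 0 for proteinase K, 3 for the trend and 1 for the interaction. Without 0.4 ng they were 5 for DASH, 4 for proteinase K and 1 for the DASH effect by RNA input, and with an estimated correlation 0 of these passed (lowest adjusted p = 0.277, 0.0624 and 0.657). In the trend, fry, which does not compare a list with other genes, turned upward for ATP synthase (limma adjusted p = 0.0003179), SPI-1 (0.01374), flagella (0.003871), heat shock genes (0.03729) and ribosomal proteins (0.3344). Without 0.4 ng the direction turned for SPI-1 in the trend (0.6911) and for tRNAs in the DASH effect by RNA input (0.001363), the median of SPI-2, which passed in neither, turned from 0.59 to -0.06 in the trend, and with library sizes alone groES had a slope of -0.0678. Among named genes 2089 comparisons with an alternative were the same, 31 stronger, 27 weaker and 1 reversed, and a sign change of a gene called in neither setting was counted as the same. Thinning to the smallest non-rRNA total lowered the genes that could be tested from 4161 to 3149 for DASH in the input series and from 3874 to 2766 for the trend, while 0 and 240 were called. At the observed counts, simulated data recovered 22% of genes changed by a log2 of 2 for DASH in the input series, 19% for proteinase K, 3% for the DASH effect by clean-up and 74% for the Bacteroides kits. For the trend 92% were recovered at a log2 of 2 per 10-fold input, which is a far larger change over the whole input range, and 42% at a log2 of 1 per 10-fold input.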

Other observations

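The tests without the 0.4 ng libraries given here were chosen only after the result was seen. In that trend with RNA input, 15 Hfq- and ProQ-associated sRNAs rose and 4 fell of 28 (median 0.55, camera adjusted p = 2.28e-05, adjusted p = 0.00343 with an estimated correlation). SPI-1 had 14 genes that rose and 8 that fell of 33, ribosomal proteins 14 and 13 of 51, and flagella 8 and 11 of 52, and none of these 3 lists lay apart from other genes (camera adjusted p = 0.691 for each). Of 835 genes called between the kits in Salmonella and 798 called in this trend, 354 were shared, 272 of them in the same direction, with 3950 genes tested in both. How many calls would be shared by chance was not tested.

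The share of table values that were exactly whole numbers, zeros included, was lower in Takara libraries, and the sources do not state whether reads of both kits were counted in the same way. In Salmonella it was 42.4 to 88.0% in NEB and 3.5 to 8.6% in Takara libraries, and in Bacteroides 61.1 to 68.9% and 1.8 to 4.1%. Genes with a count at 0.4 ng numbered 2099 after the column without DASH, 2671 after the column with DASH and 3321 after proteinase K with DASH.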
